A study of Homo sapiens with 6 samples.

How the data were processed

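KYSE-150 cells were sampled in 6 libraries, 3 with si-NC and 3 with si-circTMEM45A, assigned from the sample titles and the series design. Per the labels' protocols, total RNA was enriched for polyA RNA with oligo(dT) beads and reverse transcribed with random primers before library amplification. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.2.1, TopHat2, StringTie 2.1.6 and HTSeq were used with GRCh38; their roles and the annotation release are not given in the sources used here. The authors deposited FPKM, that is fragments per kilobase of gene scaled to library size, for 29816 Ensembl gene IDs, of which 29593 had a symbol in the names table used here.

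Multiplying each FPKM value by the GENCODE 29 union exon length and by 1 total per library gave whole reads for 100% of values (tolerance 0.001), and that total equalled the sum of the reads, 16636248 to 17323964 per library. A count model was not the main test because the deposited unit is FPKM. Pairs of replicates differed by 2.71 to 5.07 times counting noise (chi-square per degree of freedom), so no library was counted as a repeat of another.

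Genes with FPKM of at least 1 in at least 3 of the 6 libraries were tested, 12676 in all. Values were log2(FPKM + 1), which understates changes of low genes, with no further scaling. The test was limma 3.58.1 in R 4.3.3 with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The 39 gene lists, the rule for naming genes and the alternatives given first were fixed before the data were examined. Of the lists, 35 had at least 5 tested genes and were tested with camera at a preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry, which tests whether the genes of a list move in 1 direction on balance. Camera called 10 lists, 0 with an estimated correlation, and fry called 14. The variance trend in camera was not part of the fixed design. An exploratory run had used the default without it, and the default calls 9 lists. The lists were those named in the report.

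Genes were named by this rule: TMEM45A, the 12 largest changes in each direction among called genes with no overlap between groups and a mean FPKM of at least 1 in a group, the 4 smallest p-values of each called list and up to 2 called genes of each other list, the 5 genes of highest mean FPKM, and genes set apart for a closer look. From these a selection is printed. The same rule among protein-coding genes was added after the values were seen.

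The alternatives fixed in advance were pseudocounts of 0.1 and 0.5, no filter, FPKM of at least 5, TPM, median-of-ratios and quantile scaling, no variance trend, robust estimation, a replicate block and leaving out each library. Alternatives chosen after seeing the data were a filter on a mean of at least 20 recovered reads, limma voom on those reads, protein-coding genes only, camera without a variance trend and leaving out genes with a candidate seed word.

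On simulated reads for the real genes, limma recovered 18 of 50 genes given the smallest change, under 1.5-fold, then 82% at 1.5-fold, 92% at 2-fold and 100% at 4-fold, with 8 false calls among 163. Camera called the 1 list raised 1.15-fold and 0 others. This does not show how camera behaves on the real libraries. In a split of those that mixed the 2 groups, camera called 8 lists where limma called 0 genes.

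Words of 7 bases were searched in the longest annotated 3′ UTR (at least 50 bases) of 10294 tested protein-coding genes. All 16013 words found in at least 100 genes were scored against the limma statistic, adjusted for 3′ UTR length, GC content, gene length and expression, so the words were found on these data. An exploratory search with limma voom statistics preceded it. The largest absolute score in 1000 permutations of the gene labels was 5.5, and a word planted in simulated data ranked 1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.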

Results

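RNA was measured in KYSE-150, an established human esophageal squamous cell carcinoma line, after transfection of a small interfering RNA against circTMEM45A, a circular RNA named for its host gene TMEM45A, or of a control small interfering RNA called si-NC. Each group held 3 libraries of polyA-selected RNA. The deposited table gave FPKM for 29816 Ensembl genes, and the values corresponded to 16636248 to 17323964 gene-assigned reads per library. The 5 genes with the highest mean FPKM were MT-CO1, MT-CO2, MT-CO3, MT-ND4 and MT-RNR2, all encoded by the mitochondrial genome, and mitochondrial genes took 5.93 to 6.35% of the reads of each library. Libraries of one group correlated across genes at r = 0.985 to 0.988 and libraries of different groups at r = 0.978 to 0.982. The labels did not say that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

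The host gene TMEM45A (ENSG00000181458, chromosome 3, 100492619 to 100577444 in GRCh38), which encodes a transmembrane protein, was lower in each si-circTMEM45A library than in each si-NC library. Its FPKM was 3.12 ± 0.19 (SD, n = 3) with si-NC and 2.12 ± 0.22 (SD, n = 3) with si-circTMEM45A, a log2 fold change of -0.40 ± 0.08 (SE; limma adjusted p = 0.0167). An exact two-sided permutation test of the FPKM values gave p = 0.1, the smallest that 3 against 3 libraries allow. In limma the call was lost at adjusted p = 0.0614 with no filter on low values (range over the alternatives 0.000467 to 0.0614). It was also lost at adjusted p = 0.0587, 0.0569, 0.0505 and 0.0523 without si-NC replicate 1, si-NC replicate 3, si-circTMEM45A replicate 2 and si-circTMEM45A replicate 3. A gene-level value from polyA-selected RNA mostly counts the linear transcript, and the circle itself was not measured here.

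The comparison of the groups asked which genes change when circTMEM45A is targeted. Among protein-coding genes, the chemokine CCL5, the phosphatase DUSP8, the chloride channel ANO2, the actin-binding tropomyosin TPM4 and the cytokine IL6 rose, and the hair keratin KRT81, the acute-phase protein SAA1, the lysyl oxidase LOXL4, the activin antagonist FST and the cytokine IL1B fell. CCL5 had a mean of 4.47 FPKM with si-NC and 12.5 with si-circTMEM45A, a log2 fold change of 1.32 ± 0.17 (SE, n = 3). TPM4, the most abundant of these, went from 28.8 ± 0.40 to 59.6 ± 1.36 FPKM (SD, n = 3). KRT81 went from 10.8 ± 1.07 to 3.24 ± 0.49 FPKM and SAA1 from 8.14 ± 0.18 to 2.90 ± 0.76. In all, 2380 of 12676 tested genes passed an adjusted p of 0.05 in limma, 1411 higher and 969 lower with si-circTMEM45A. Most changes were small, with a median absolute log2 fold change of 0.29, and 34 genes changed at least 2-fold on the log2(FPKM + 1) scale, 24 up and 10 down. That number moved with the setting, to 72 genes at a pseudocount of 0.1, 71 with TPM, 118 with limma voom, 9 at FPKM of at least 5, 11 with a filter on 20 recovered reads and 10 when only protein-coding genes were tested. The 2 groups did not overlap for 39.2% of tested genes, against 10% by chance. With median-of-ratios scaling the split was 1078 higher and 1206 lower, and with quantile normalization 1119 higher and 1168 lower. With fewer libraries in each fit the counts dropped. Without si-NC replicates 1, 2 and 3 in turn, 835, 821 and 879 genes were higher and 591, 548 and 594 lower. Without si-circTMEM45A replicates 1, 2 and 3 in turn, 1088, 798 and 775 were higher and 857, 573 and 566 lower.

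**Figure D1:**
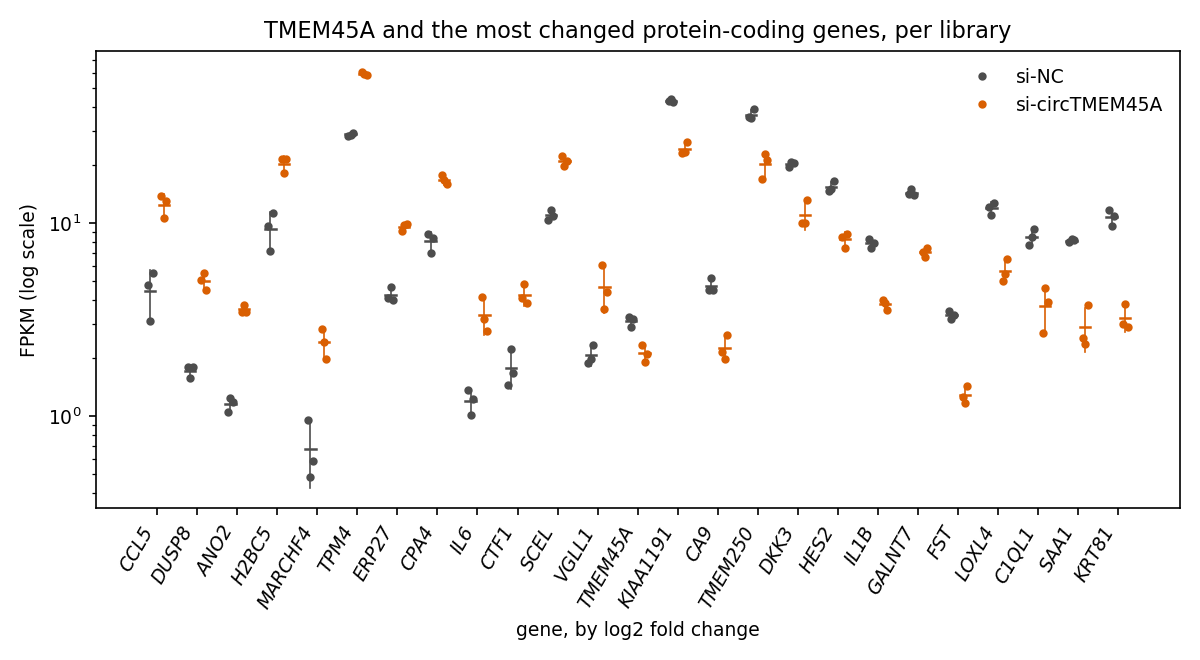
FPKM on a log axis of TMEM45A and 24 protein-coding genes in the 3 si-NC and 3 si-circTMEM45A libraries. The 24 are the 12 largest increases and the 12 largest decreases in log2 fold change by the naming rule. Points are libraries, horizontal bars means and vertical bars 1 SD. The groups do not overlap for any of the 25 genes, which the naming rule required of the 24. TMEM45A, named whatever its values, lies at 3.12 against 2.12 FPKM on average.

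Of the 12 genes with the largest increases by the rule fixed in advance, CCL5, DUSP8 (1.72 ± 0.13 to 5.03 ± 0.52 FPKM; SD, n = 3), ANO2 (1.16 ± 0.10 to 3.58 ± 0.18) and the antisense RNA gene MAN1B1-DT (log2 fold change 1.19 ± 0.09; SE) rested on more than 50 reads per library on average. The others were MIR331, MIR4531, SNORA16B, MIR3177, MIR6889, MIR5700, RNU6-195P and SPACA7BP. The 12 genes with the largest decreases were SNORD19, RNU6-130P, KRT81, SNORD99, SAA1, RPL7AP82, MIR548AT, C1QL1 (8.52 ± 0.81 to 3.75 ± 0.98 FPKM), LOXL4 (log2 fold change -0.97 ± 0.09; SE), MIR563, FST (3.35 ± 0.18 to 1.29 ± 0.13) and GALNT7, a glycosyltransferase (14.3 ± 0.56 to 7.09 ± 0.39). In these 24, 14 genes were under 300 bases long and rested on a median of 2.92 reads per library, so their fold changes carry large counting error. In limma MIR331, SNORA16B, MIR6889, SPACA7BP, SNORD19 and MIR563 each lost their call in 5 of the 6 fits that left out 1 library (adjusted p 0.0546 to 0.127). The exceptions were the fit without si-circTMEM45A replicate 1 for MIR331 and SNORD19, without si-NC replicate 2 for SNORA16B and MIR6889, and without si-NC replicate 3 for SPACA7BP and MIR563. RNU6-130P lost its limma call without si-NC replicate 1 or 3 or si-circTMEM45A replicate 1 or 2 (adjusted p 0.0641 to 0.0813). MIR3177 lost it without any 1 si-circTMEM45A library (limma adjusted p 0.0741 to 0.11), and RNU6-195P without si-NC replicate 3 or si-circTMEM45A replicate 2 or 3 (limma adjusted p 0.0553 to 0.0738). MIR4531, MIR548AT and SNORD99 lost no call in these fits, but that does not make them firm. Their mean reads with si-NC and si-circTMEM45A were 0 and 1.33, 1.33 and 0, and 4.67 and 1. Applying the rule to protein-coding genes alone was decided after the values were seen. It added H2BC5, MARCHF4, TPM4, ERP27, CPA4, IL6 (1.21 ± 0.18 to 3.37 ± 0.72 FPKM), CTF1, SCEL and VGLL1 among the genes that rose, and IL1B (7.89 ± 0.44 to 3.80 ± 0.22), HES2, DKK3, TMEM250, CA9 and KIAA1191 among those that fell. The rule took only genes past the limma threshold and without overlap between groups. The limma adjusted p of these 15 genes lay between 9.06e-05 and 0.0107. VGLL1 was no longer called in limma with no filter on low values. KRT81 and SAA1 have near-identical relatives between which reads can be split, so their values are uncertain. Of the 969 lower genes 61 had no searched 3′ UTR, and of the other 908, 514 held at least 1 of the 7-base words TGAAAGC, GAAAGCA, CCTGATC or CTGATCA in it, against 3071 of 8169 genes not called. The words were picked from these data. Of the 12 protein-coding genes with the largest decreases, SAA1, FST, GALNT7, HES2, TMEM250 and KIAA1191 were among those 514. The others, KRT81, C1QL1, LOXL4, IL1B, DKK3 and CA9, held none of the words. Of the 12 with the largest increases, SCEL and VGLL1 held at least 1.

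In these libraries of polyA-selected RNA, replication-dependent histone genes rose as a group. PolyA selection leaves out most transcripts without a poly(A) tail, so the rise covers only the histone RNA that was captured. Of 20 tested, 10 rose and 0 fell, also when adjusted over the list alone, with a median log2 fold change of 0.40 (camera adjusted p = 1.3e-05, and adjusted p = 0.38 with an estimated correlation). H2BC12 rose from 112 ± 3.01 to 191 ± 2.03 FPKM (SD, n = 3), H2AC6 from 24.7 ± 1.56 to 37.4 ± 1.43, H2BC21 from 2.15 ± 0.16 to 4.67 ± 0.47 and the linker histone H1-2 from 36.2 ± 1.85 to 48.6 ± 0.71. Histone genes share near-identical coding sequences, so reads can be split between copies. Some members below the expression filter, picked after their values were seen, had lower means with si-circTMEM45A, such as H4C3 at 1.09 against 0.22 FPKM and H2AC4 at 0.71 against 0.05. Of 18 immediate early genes tested, which encode transcription factors and regulators induced within minutes of a stimulus, 8 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.0387, and adjusted p = 0.38 with an estimated correlation). The AP-1 subunit JUN rose from 13.7 ± 0.97 to 25.2 ± 0.52 FPKM, JUND from 40.7 ± 3.00 to 54.2 ± 4.76, ATF3 from 20.5 ± 0.33 to 27.2 ± 1.87 and KLF6 from 10.2 ± 0.46 to 13.6 ± 1.26. The median log2 fold change of the immediate early list was 0.13. The call for immediate early genes was lost with the default variance setting of camera, at adjusted p = 0.0628, and without si-NC replicate 1 or si-circTMEM45A replicate 3, at camera adjusted p = 0.0627 and 0.086.

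The G2/M, ribosomal protein and WNT and NOTCH lists were called lower by camera, although 20 of 32, 52 of 74 and 12 of 19 of their tested genes did not pass in limma over all genes. Their median log2 fold changes were -0.13, -0.09 and -0.21, and the genes named below were chosen for small p-values. Of 32 G2/M genes, 12 fell and 0 rose, and 17 fell and 1 rose when adjusted over the list alone (camera adjusted p = 5.7e-09, and adjusted p = 0.38 with an estimated correlation). The mitotic kinase AURKA fell from 67.3 ± 0.18 to 55.9 ± 0.85 FPKM (SD, n = 3) and CENPF, a kinetochore protein, from 96.7 ± 3.06 to 82.2 ± 2.13. The topoisomerase TOP2A had a log2 fold change of -0.24 ± 0.03 (SE). Of 74 cytosolic ribosomal protein genes, 22 fell and 0 rose, and 28 fell when adjusted over the list alone (camera adjusted p = 2.1e-10, and adjusted p = 0.47 with an estimated correlation). RPS13 fell from 119 ± 8.12 to 75.2 ± 4.67 FPKM and RPL12 from 314 ± 13.3 to 245 ± 4.89. These genes have many processed pseudogenes that can take their reads, and with fry the list was not called (adjusted p = 0.0595). Of 19 WNT and NOTCH genes, 7 fell and 0 rose, and 12 fell and 1 rose when adjusted over the list alone (camera adjusted p = 4.3e-06, and adjusted p = 0.38 with an estimated correlation). The cyclin CCND1 fell from 59.1 ± 4.04 to 37.7 ± 2.01 FPKM and DKK3, a secreted WNT modulator, from 20.3 ± 0.64 to 11.1 ± 1.81. The receptor NOTCH2 had a log2 fold change of -0.45 ± 0.05 (SE).

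Of 20 NRF2 target genes, which act in redox defence, 8 fell and 1 rose, and 9 fell and 2 rose when adjusted over the list alone (camera adjusted p = 0.00054, and adjusted p = 0.38 with an estimated correlation). The ferritin light chain FTL fell from 374 ± 17.8 to 260 ± 15.9 FPKM (SD, n = 3) and the cystine transporter SLC7A11 from 6.34 ± 0.44 to 4.60 ± 0.38. Of 17 antigen presentation genes, 5 fell and 2 rose, and 6 fell and 2 rose when adjusted over the list alone (camera adjusted p = 0.0132, and adjusted p = 0.44 with an estimated correlation). The immunoproteasome subunit PSMB10 fell from 9.95 ± 0.48 to 5.76 ± 0.33 FPKM, and the peptide-trimming enzymes ERAP1 from 4.24 ± 0.22 to 2.61 ± 0.17 and ERAP2 from 4.99 ± 0.20 to 3.37 ± 0.25. Of 34 S phase genes, 3 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.0242, and adjusted p = 0.50 with an estimated correlation); the replicative helicase subunit MCM3 fell from 121 ± 3.24 to 90.6 ± 4.63 FPKM. Of 29 DNA repair genes, 7 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.0288, and adjusted p = 0.47 with an estimated correlation), among them TOP2A, which is also a G2/M gene. Of 24 hypoxia response genes, 7 fell and 1 rose, and 8 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.0391, and adjusted p = 0.42 with an estimated correlation). The carbonic anhydrase CA9 fell from 4.75 ± 0.41 to 2.26 ± 0.33 FPKM and BHLHE40 from 28.1 ± 0.92 to 18.7 ± 0.61. As lists the shifts were small. The median log2 fold change was -0.15 for NRF2 targets, -0.12 for antigen presentation, -0.07 for S phase, -0.04 for DNA repair and -0.07 for hypoxia response. The calls for S phase and E2F targets, DNA repair, hypoxia response and immediate early genes were lost, at camera adjusted p = 0.0794, 0.176, 0.163 and 0.195, when genes with one of the 4 words above were left out. The words were picked because genes that hold them tended to fall. The genes left out were 514 called lower, 328 called higher and 3071 not called. Without these genes the median log2 fold change of all tested genes moved from 0.03 to 0.05, so the losses do not show that the words carry the list changes. Fry did not call S phase (adjusted p = 0.138) or DNA repair (adjusted p = 0.0517), and with FPKM of at least 5 camera did not call antigen presentation (adjusted p = 0.0897) or hypoxia response (adjusted p = 0.186). Without si-NC replicate 1, S phase and DNA repair were lost at camera adjusted p = 0.127 and 0.0627. Without si-circTMEM45A replicate 1, S phase and hypoxia response were lost at 0.0687 and 0.0517 in camera. Hypoxia response was also lost without si-NC replicate 3 and without si-circTMEM45A replicate 2, at camera adjusted p = 0.0676 and 0.0546, and DNA repair without si-circTMEM45A replicate 3, at 0.0797.

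**Figure D2:**
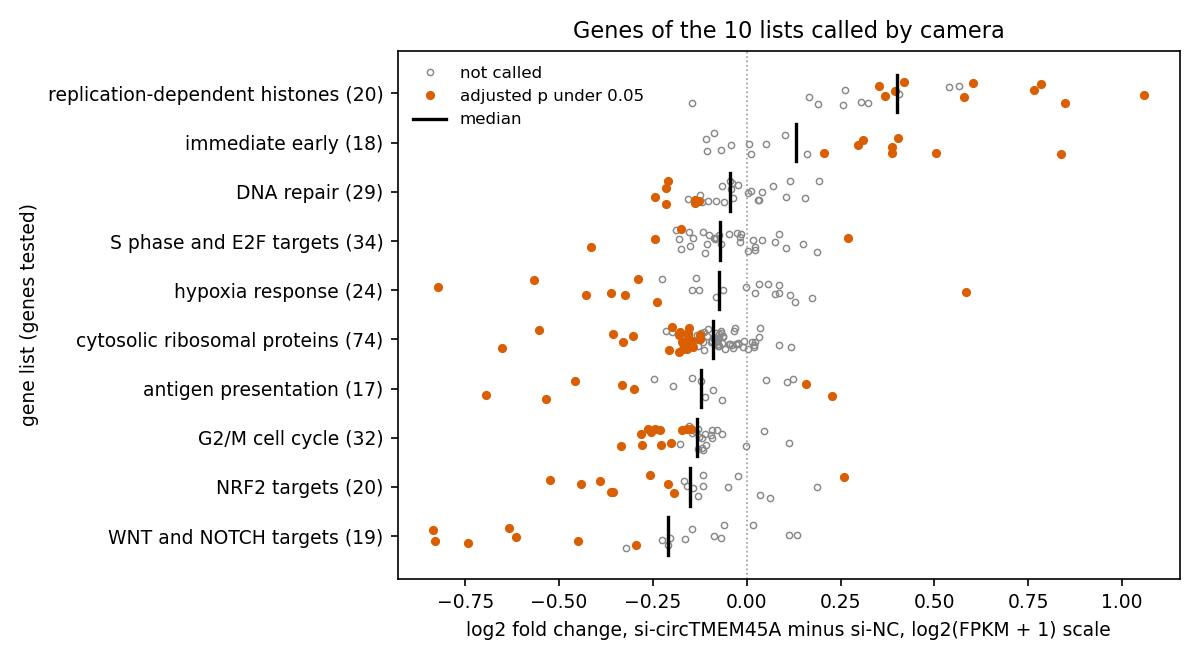
Log2 fold change on the log2(FPKM + 1) scale of each tested gene in the 10 lists called by camera; filled points passed an adjusted p of 0.05 in limma over all genes, open points did not, and black bars are medians. The histone median lies at 0.40 and the WNT and NOTCH median at -0.21.

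The remaining 25 tested lists were not called by camera. Fry called 7 of them, squamous differentiation (adjusted p = 0.0317), basal squamous and stem-like (0.0317), oxidative phosphorylation (0.0207), unfolded protein response (0.0275), TGF-beta targets (0.0104), YAP/TAZ targets (0.0292) and autophagy and lysosome (0.00117). Camera gave basal squamous and stem-like genes an adjusted p of 0.0574 and called them lower under 7 alternatives, including the replicate block (0.0379) and the fits without si-NC replicate 2 (0.0335), si-circTMEM45A replicate 2 (0.0463) or si-circTMEM45A replicate 3 (0.0419). Without genes with a candidate seed word, camera called apoptosis (adjusted p = 0.0371) and the unfolded protein response (0.031) higher. Camera also called the unfolded protein response without si-NC replicate 1 (adjusted p = 0.03) or si-circTMEM45A replicate 2 (0.0463), YAP/TAZ targets without si-circTMEM45A replicate 2 (0.0463), and autophagy and lysosome without si-NC replicate 2 (0.0477) or si-circTMEM45A replicate 3 (0.048). With no filter on low values camera called oxidative phosphorylation (adjusted p = 0.0168), the unfolded protein response (0.0109), YAP/TAZ targets (0.0456), autophagy and lysosome (0.0196) and small interfering RNA and circular RNA machinery (0.0248). Among basal squamous and stem-like genes 7 of 17 fell and 2 rose. Those that fell included the basal keratins KRT5 (360 ± 11.6 to 238 ± 10.6 FPKM, SD, n = 3) and KRT14 (10.7 ± 0.57 to 6.47 ± 0.30). The 2 that rose, named after their values were seen, were the keratin KRT17 (70.5 ± 4.28 to 98.7 ± 5.89) and LAMB3 (68.3 ± 2.04 to 75.5 ± 2.24). Among squamous differentiation genes 2 of 12 rose and 0 fell, these being the cornified envelope protein SCEL (log2 fold change 0.88 ± 0.06; SE) and S100A9 (4.30 ± 0.89 to 7.47 ± 1.31 FPKM). Of 19 MAPK and EGFR genes 4 rose and 2 fell, with the receptor EGFR at 58.5 ± 1.68 and 37.6 ± 0.29 FPKM. Of 22 YAP/TAZ targets 5 rose and 8 fell, and of 27 autophagy and lysosome genes 8 rose and 1 fell. Of 19 mesenchymal genes 4 rose and 5 fell, with the matrix protein THBS1 at 125 ± 3.92 and 72.0 ± 1.98 FPKM. Of 21 NF-kB and inflammatory genes 4 rose and 5 fell, and of 29 interferon response genes 7 rose and 6 fell. Of 28 ATF4 and amino acid response genes 3 rose and 4 fell, including the amino acid transporter SLC7A5 (1231 ± 42.6 to 820 ± 66.3 FPKM). Counts of genes that rose and fell were 6 and 3 of 21 for apoptosis, 5 and 0 of 20 for the unfolded protein response, 6 and 1 of 17 for TGF-beta targets, 4 and 2 of 21 for epithelial junction, 1 and 2 of 23 for p53 targets and 4 and 3 of 28 for MYC targets. They were 3 and 1 of 34 for oxidative phosphorylation, 2 and 4 of 19 for glycolysis, 2 and 0 of 13 for mitochondrially encoded genes, 2 and 1 of 16 for heat shock, 3 and 1 of 16 for ferroptosis, 0 and 3 of 22 for cholesterol biosynthesis and 3 and 2 of 20 for fatty acid metabolism. They were 3 and 5 of 29 for JAK-STAT3 and PI3K-AKT-mTOR, 1 and 4 of 28 for small interfering RNA and circular RNA machinery and 2 and 1 of 9 for TMEM45 and neighbours on 3q12. Markers of other cell types were too few to test as lists. Of 4 fibroblast markers tested PDPN (9.64 ± 0.56 to 7.19 ± 0.59 FPKM) and FBLN1 (9.04 ± 0.76 to 6.44 ± 0.85) fell, of 4 columnar markers MUC1 rose (2.09 ± 0.33 to 2.86 ± 0.07), the 1 endothelial marker tested did not pass, and 0 of 19 immune markers reached the filter. S100A9, FBLN1 and MUC1 lost their limma calls when single libraries were left out: S100A9 without si-circTMEM45A replicate 2 (adjusted p = 0.0611), FBLN1 without si-NC replicate 3 (0.0627) or si-circTMEM45A replicate 2 (0.054), and MUC1 without any library but si-NC replicate 2 (0.0852 to 0.129). Adjusted over the list alone, counts of higher and lower genes differed from these for some lists. They were 6 and 9 for basal squamous, 5 and 2 for epithelial junction, 4 and 6 for mesenchymal, 4 and 3 for p53, 7 and 3 for apoptosis, 2 and 0 for oxidative phosphorylation, 7 and 7 for interferon and 6 and 2 for the unfolded protein response. They were 3 and 5 for ATF4, 4 and 2 for ferroptosis, 5 and 9 for YAP/TAZ, 4 and 3 for MAPK and EGFR, 4 and 7 for JAK-STAT3, 3 and 2 for 3q12, 0 and 3 for fibroblast and 0 and 1 for endothelial markers. For the other lists the counts adjusted over the list alone were equal. The sign of the median differed from that of the mean or of the camera test for mesenchymal, p53, interferon, NF-kB, ATF4, heat shock and fatty acid genes. Under another scaling the median turned sign for mesenchymal, p53, glycolysis, mitochondrially encoded, MYC, NF-kB and ATF4 genes.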

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

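Genes in this part were picked after seeing the data, as genes below the expression filter that limma voom called with an absolute log2 fold change of at least 2, a limit set after the values were seen. They were set apart because they lie outside the genes tested in the report and had more reads with si-circTMEM45A than with si-NC. TENM4, a teneurin (chromosome 11), went from 6 to 80.7 reads per library on average, a limma voom log2 fold change of 3.63 ± 0.35 (SE; adjusted p = 3.7e-08). MYPN, a muscle sarcomere protein (chromosome 10), went from 8.67 to 63 reads, a log2 fold change of 2.81 ± 0.38 (limma voom adjusted p = 5.0e-06). ADGRL2, an adhesion receptor (chromosome 1), went from 9 to 59.3 reads, a log2 fold change of 2.64 ± 0.33 (limma voom adjusted p = 1.9e-06). NAALADL2 (chromosome 3) went from 11.3 to 57.3 reads, a log2 fold change of 2.38 ± 0.40 (limma voom adjusted p = 9.2e-05). Their mean FPKM stayed between 0.02 and 0.52.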

How the results depend on the processing

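The alternatives with recovered reads, with protein-coding genes only, without candidate seed words and with camera's default variance setting were chosen after seeing the data. No gene or list called in the report was called in the opposite direction under an alternative. The larger of the counts by direction did turn, from 1411 higher and 969 lower to 1078 higher and 1206 lower with median-of-ratios scaling and 1119 higher and 1168 lower with quantile normalization, and the medians of 7 lists that were not called turned sign under a scaling. The count of higher genes was 728 with no filter on low values and 859 without genes with a candidate seed word, and 775 to 1088 when each library was left out. The count of lower genes was 526 with no filter, 1454 with limma voom on recovered reads, 367 without genes with a candidate seed word, and 548 to 857 when each library was left out. Of the genes called by limma on FPKM, 2233 were called by limma voom, all in the same direction. Genes changed at least 2-fold numbered 72 with a pseudocount of 0.1, 9 with FPKM of at least 5, 71 with TPM, 11 with a filter on 20 recovered reads, 118 with limma voom, 10 among protein-coding genes, and 28 to 40 when each library was left out. Gene lists called numbered 0 with an estimated correlation, 9 with the default variance setting of camera and 8 to 12 when each library was left out. TMEM45A kept a log2 fold change of -0.40 with no filter, no longer past the limma threshold (adjusted p = 0.0614; 0.000467 to 0.0614 over the alternatives), and -0.45 to -0.35 when each library was left out; it was not tested at FPKM of at least 5. A stricter or absent filter changes the number of genes tested, and leaving out libraries reduces the samples; otherwise the cause was not tested. The median log2 fold change of the 10 called lists kept its sign under the 3 scalings. Summed over lists and alternatives, calls were lost 29 times and gained 32 times, and summed over named genes and alternatives, lost 151 times and gained 4 times. Deviations of same-numbered libraries correlated at r = 0.026, 0.011 and 0.047, and those of differently numbered libraries at -0.046 to 0.018. These weak values do not settle whether same-numbered libraries shared a culture or day. With the replicate block 1000 genes were higher and 720 lower. Genes with few reads are limited by counting error, and 940 tested genes had a mean under 20 reads.

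None of the other splits of the 6 libraries into 3 and 3 called a gene in limma, against 1411 higher, 969 lower and 34 changed at least 2-fold in the real split, which was 1 of 10. For gene lists the real value was 10 and the highest of the other splits 8, again with 1 of 10 splits as large. With 10 splits a share under 0.05 cannot be reached. Every other split also puts libraries of both groups on each side, so the difference between the groups widens the spread within each side. Few gene calls were therefore to be expected there, and their absence does not measure how many calls arise by chance.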

Other observations

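The tests in this part chosen after the result was seen were the scan of back-splice windows, the adjustment for 3′ UTR length and composition, the counts of places in circles, the rank of the control duplex words and the histone median without 3 genes; the order of site types, the comparison with coding sequence, the small RNA median, the share of histone genes with a word and the splits were set before.

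Genes lower with si-circTMEM45A shared words in their 3′ UTRs. The 4 lowest-scoring of 16013 words were CTGATCA (z = -10.3), GAAAGCA (z = -10.3), CCTGATC (z = -9.5) and TGAAAGC (z = -9.4), against an absolute z of 4.6 that 5% of permutations exceeded. At least 1 of them was held by 56.6% of lower genes and 37.6% of genes not called. The odds ratio was 2.17 (95% interval 1.88 to 2.49; Fisher's exact test, two-sided, p = 5.0e-28), for genes that are not independent and words picked from them. The share called lower was 17.1% of genes with a full 8-base site and 11.7% of genes with a 7-base site only. It was 7.3% of genes with the 6-base core only and 6.9% of genes with a word in coding sequence only. Of genes with none of these, 5.4% were called lower. The odds ratio and these shares were not adjusted for 3′ UTR length or composition.

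A candidate explanation is seed pairing by both strands of a small interfering RNA across the TMEM45A back-splice: the 19-base window TGCTTTCATTACCTGATCA joins the last 15 bases of the exon at chromosome 3, 100568822 to 100568967, to the first 4 of the exon at 100555209 to 100555401 (GRCh38), and the words are sites of positions 2 to 8, or 2 to 7 followed by an A, of its strands. Its summed z was -39.5, the lowest of 2367 back-splice windows, against -22.2 for the next, -9.3 for the lowest sharing no word with it and -21.6 for the lowest of 6070 linear windows. Against other accounts, the strongest word, CTGATCA, went from z = -12.1 to -10.3 with 3′ UTR length, GC content, gene length and expression in the model, still beyond the permutation limit, and 0 of the 73 circles that annotated TMEM45A exons can close hold a place of TGAAAGC or GAAAGCA at which a small RNA could have been bound. Open are release of a small RNA at CCTGATC, which 31 of these circles hold at 1 place (overlapping words counted once, a rule set after the count was seen), circles with introns, which were not searched, and the kind of site: genes with the 8-base site lay -0.069 from those with the 6-base core in median log2 fold change (-0.055 adjusted), and the shift with coding sequence words was 0.42 ± 0.09 (bootstrap SE) of that with 3′ UTR words (0.23 ± 0.11 adjusted, against a limit of 0.5), but the words were picked from these genes, so neither value decides. The labels give neither the sequence used nor the position of the circle, so an effect of losing the circle stays open and untested. The real split gave 10.3 against at most 6.9 in the others, 1 of 10, too few for a share under 0.05. The other splits mix libraries of both groups on each side, so they do not show what score arises by chance.

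Genes higher with si-circTMEM45A shared other words, led by TCGGAGA (z = 6.5) and CGGAGAA (z = 6.4), less than the largest absolute z of 6.9 for a word in another split of the libraries. These are seed sites of 1 strand of TTCTCCGAACGTGTCACGT, a widely sold negative-control duplex known from general knowledge. Of higher genes with a searched 3′ UTR 16.6% held at least 1 of 4 site words of this duplex, against 9.6% of genes not called. The test of this duplex was chosen after the words were seen, so this contrast is not independent evidence for it. The shares were not adjusted for 3′ UTR length. Among the 12 protein-coding genes with the largest increases, TPM4 and H2BC5 held a word. CCL5, DUSP8, ANO2, MARCHF4, ERP27, CPA4, IL6, CTF1, SCEL and VGLL1 held none. In 1 of the words, GTCACGA, the last A does not pair with the strand. Seed pairing of both strands of a widely sold negative-control duplex in the si-NC libraries may contribute, since the worse of the strands had its best word, TGTCACG, at rank 5, although its z of 4.4 lay within the permutation limit of 4.6. The labels do not say which control was used, and an effect of the circle on these genes stays open.

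The rise of histone genes was set against technical accounts. Small nuclear, nucleolar and Cajal body RNA genes, which mostly lack poly(A) tails, had a median limma voom log2 fold change of -0.07 ± 0.14 (bootstrap SE) over 6 genes, below the rise of 0.2 set for carry-over of such RNA. With 6 genes, this spread and RNA of other kinds than histone RNA, the value does not decide whether histone RNA without a poly(A) tail was carried over. The median of the 20 tested histone genes stayed at 0.37 without the 3 most changed. A median moves little when 3 of 20 genes are left out, so this value says little against an account by a few genes. Whether a single gene cluster carried the rise was not tested. Of the called histone genes 8 had an annotated 3′ UTR, and 1 of these (12.5%) held a word of the control duplex. Reads shared between histone copies and an effect of circTMEM45A were not tested and stay open.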
